A study of Mus musculus with 16 samples.

How the data were processed

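The series holds 16 one-colour expression arrays of cultured mouse cortical cells, 4 in each of 4 groups: neuron control, neuron Klotho, astrocyte control and astrocyte Klotho. Per the labels' protocols, cultures received 1 nM recombinant secreted Klotho or phosphate-buffered saline for 24 h, RNA was extracted with a silica column kit, and 200 ng of total RNA was labelled with Cy3. Groups were taken from the sample titles and the treatment field. Samples were treated as independent within a group, and the labels record neither culture batches nor the sex of the animals.

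Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 12.0.3.1 under protocol GE1_1200_Jun14 from array design 028005, with probes placed on mouse build NCBI37. Their signal columns are linear intensity values, per the file headers, and the processed intensity is background-subtracted and detrended within the array but not normalized between arrays. Flags of 0 or 1 per spot mark signals well above background, saturation and outliers. The deposited value table states no unit, and its values have a mean of 0 and an SD of 1 in each column, so they are a score. Each of its 16 columns equals the z-score of log2 processed intensity of 1 scanner array to within 0.005, and the next best array differs by at least 1.666. Of these columns 10 match the array of their own sample and 6 that of another astrocyte sample. Which source is right could not be settled from the deposit. The scanner file assignment was used throughout, and the astrocyte comparisons were repeated with the value table assignment. No column of per-sample values from any file stayed unused (0 others).

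Each array holds 62976 spots, of which 3671 are controls and 59305 represent 55681 probes. Spots that Feature Extraction called population outliers were dropped and the remaining spots of a probe averaged. The log2 processed intensity was centred on the 75th percentile of the array's non-control probes, so a level of 0 is that percentile. A probe counted as well above background on an array when at least 0.5 of its spots did. Probes were named through their RefSeq accession, matched without version to a RefSeq gene table of assembly GRCm38.p6, since the files carry no gene symbol. Of all probes 29786 carry such an accession, 28331 (50.9%) received a symbol, and 1455 have an accession absent from the table. The other 27350 probes stayed in the tests without a symbol. The brightest probe stood for each symbol, which left 26136 units that were above background in at least 1 comparison, 16562 of them with a symbol. No spot was saturated (0 per array).

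Depth was judged by signal over background. Spots well above background numbered 38541 to 39934 per neuron control array, 34357 to 36751 per neuron Klotho array, 36729 to 39605 per astrocyte control array and 34120 to 39890 per astrocyte Klotho array. Arrays of a group correlated with r between 0.943 and 0.996, and no samples were identical. The median SE of a log2 change was 0.166 in neurons, 0.325 in astrocytes and 0.297 between the controls.

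Each comparison included units well above background on all 4 arrays of at least 1 compared group. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The comparisons were Klotho against control within neurons and within astrocytes, the difference of these effects by an interaction term over all 16 arrays, and astrocyte control against neuron control. A gene that was not above background on any array of 1 group has a bound in place of a fold. For the bound, the mean of that group was taken from the higher of each array's own signal and its lowest signal well above background. Gene lists were tested with camera (preset correlation 0.01, lists with at least 5 tested genes), beside camera with the correlation estimated per list and the rotation test fry. With the correlation estimated, camera called 0 lists in every comparison, also between the controls, where 13848 genes differed. A call lost in that test is therefore by itself no evidence that a list did not change. List means were compared by exact permutation over the 70 arrangements of 8 arrays. The 43 lists, 33 of pathways and 10 of cell types, were fixed together with the comparisons, thresholds, alternatives and rule for naming genes before the data were examined. Overlap with the liver list was tested with Fisher's exact test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for preparation, overlap and figures.

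Genes were named by the fixed rule. It covers Kl, Klb and the FGF receptor genes, up to 10 called genes per direction with the largest change on arrays where all values are above background, and up to 10 genes with the smallest p where fewer pass. It adds up to 4 members per described list with the smallest p, up to 3 genes per direction with the largest bound, up to 4 marker genes per cell type between the controls and up to 5 genes per direction for the interaction. Some genes that the rule covers are not reported here. Other named genes are said to have been chosen after their values were seen. After the neuron result 5 lists of organ genes were added. Adult liver had 29 of 60 tested genes lower in neurons (median -2.22). Embryonic liver and red cells had 0 of 5 (median 0.02), kidney 0 of 5 (-0.05), skeletal muscle and heart 0 of 13 (-0.10), and intestine and pancreas 0 of 6 (-0.06), none called by limma.

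Replicate numbers were checked for pairing through the correlation of deviations from the group means. Same-numbered neuron arrays correlated with r = 0.778, 0.173, 0.472 and 0.408, and astrocyte arrays by scanner file with 0.724, 0.181, 0.526 and 0.621. By the rule that every pair exceeds 0.1 the numbers count as pairs. The best match carried the same number for 5 of 8 neuron and 7 of 8 astrocyte arrays. Same-numbered arrays also share the slide column in neurons, and the slide row and column in astrocytes by scanner file. Pairing of samples therefore cannot be told apart from array position. The pairing comes from the data, since the labels do not mention it. By value table the astrocyte values were 0.023, -0.733, 0.627 and -0.282, and between the controls they were 0.072, 0.072, -0.151 and 0.263, which is no pairing. The fitted comparisons have no block, and a fit with the replicate number as a block was run beside each.

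The fixed alternatives were another background correction (normexp with an offset of 50, run on the median spot signal because the files lack the mean signal), quantile and median scaling, no background filter, a filter on all arrays, the mean over a gene's probes, and the deposited values. Others shared the spread over all 16 arrays, modelled its trend, blocked on the replicate number, or left out each array in turn. All neuron arrays share slide 1, where treatment is confounded with array row. By scanner file, slide is confounded with treatment in astrocytes and with cell type between the controls, so a slide block could not be fitted there. By value table, treatment is confounded with slide column. The fitting steps were tested on simulated data with known changes. Noise was drawn independently for each gene and array, without the row structure or pairing of the real arrays, so the shares hold for that setting only. In neurons 52% of genes changed by 1 on the log2 scale and 86% of those changed by 2 were recovered, with 12 false calls among 24724 genes. Between the controls these shares were 8% and 60% (4 false calls), and for the interaction 6% and 48% (3 false calls).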

Results

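Gene expression was profiled in primary cultures of mouse cerebral cortex after exposure to secreted Klotho, a circulating protein best known as a co-receptor for the hormone FGF23. Cultures of neurons and of astrocytes received 1 nM recombinant Klotho or phosphate-buffered saline for 24 h, which gave 4 groups of 4 arrays. Neurons came from cortex of embryonic day 16 and were treated after 14 days in vitro. The growth protocol takes astrocytes from pups of postnatal day 0 to 5 and states a purity above 98% after 15 h of shaking, although the labels of the astrocyte samples also carry embryonic day 16. The labels do not say whether the 4 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The title of the series concerns Klotho and aerobic glycolysis of astrocytes, the conversion of glucose to lactate in the presence of oxygen, and the comparisons ask which genes differ with Klotho in each cell type.

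RNA was hybridised to 16 one-colour arrays with 59305 spots for transcripts each. Spots well above background made up 66.6% ± 1.07 (SD, n = 4) in neuron control, 59.4% ± 1.83 in neuron Klotho, 64.3% ± 2.05 in astrocyte control and 62.1% ± 4.02 in astrocyte Klotho arrays. The number of arrays limits the precision, and log2 fold changes are given with their standard error. The deposit assigns the astrocyte arrays in 2 ways that conflict. The deposited value table holds 1 column per sample, and each column equals the scaled signal of 1 scanner file to within 0.005. All 8 neuron columns match the scanner file of their own sample, but 6 of the 8 astrocyte columns match the file of another sample, and 4 of these come from the other treatment. Astrocyte results are therefore given by scanner file, the assignment used for every count unless stated otherwise, and by value table. By scanner file the astrocyte control arrays lay on slide 2 and the Klotho arrays on slide 3, while by value table each of these slides held 2 arrays of each treatment, with all 4 controls in slide column 3 and all 4 Klotho arrays in column 4. Treatment therefore cannot be told apart from slide under the first assignment or from slide column under the second.

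In neurons the genes that differed between Klotho and vehicle were mostly genes of the liver, 29 of 37 by a list drawn up after the result was seen, and every one was lower in the Klotho arrays. Alb, which encodes serum albumin, was at least 51.8-fold lower, the fetuin gene Ahsg at least 25.5-fold and the major urinary protein gene Mup18 at least 14.2-fold (adjusted p = 0.000834 each, limma). The alpha-1-antitrypsin genes Serpina1a, Serpina1c and Serpina1e were measured on all 8 arrays and fell by 5.63 ± 0.36, 5.37 ± 0.35 and 5.05 ± 0.34 on the log2 scale (SE, n = 4 per group, adjusted p = 0.000834 each). Fbp1, the fructose-1,6-bisphosphatase of gluconeogenesis, fell by 1.49 ± 0.16 (adjusted p = 0.0110), from a mean of -2.79 ± 0.14 (SD) relative to the array's 75th percentile to -4.29 ± 0.30. The plot of liver-expressed and glycolytic genes shows these values per array.

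**Figure D1:**
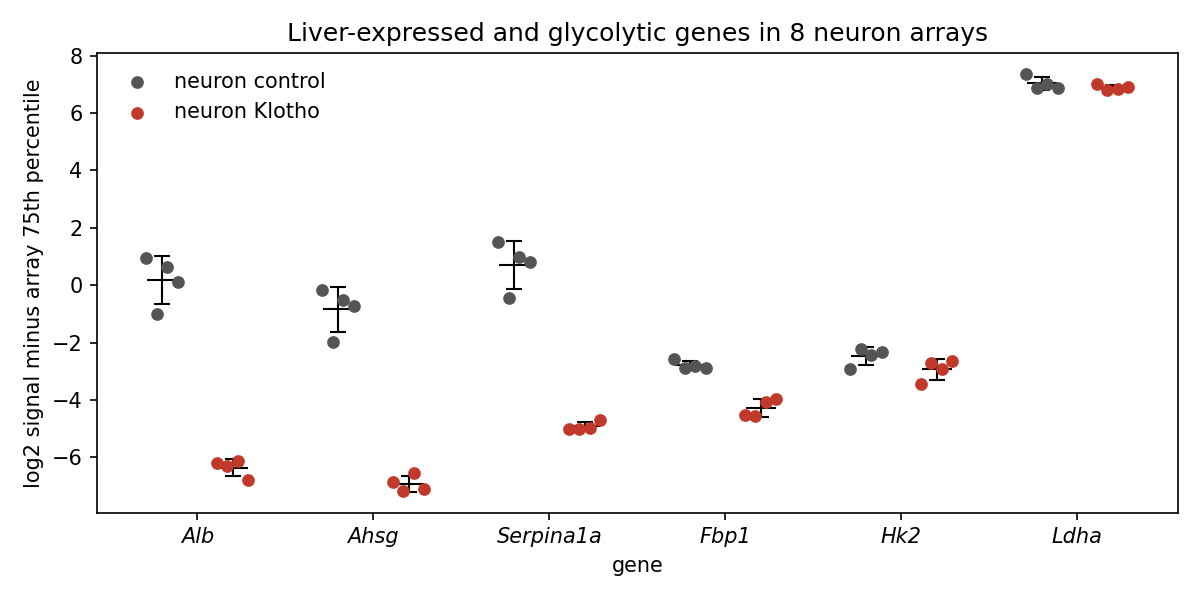
Level of 6 genes on the 8 neuron arrays, as log2 signal minus the array's 75th percentile. Points are arrays (4 control, 4 Klotho), and bars give the mean ± SD. Alb, Ahsg, Serpina1a and Fbp1 lie lower on all 4 Klotho arrays, while Hk2 (log2 change -0.46) and Ldha (-0.14) did not pass the test. Alb and Ahsg were not well above background on any Klotho array.

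Of 24724 genes tested in neurons, 37 were lower with Klotho and 0 higher by limma, and 1067 (4.32%) had an unadjusted p below 0.05. In all 37 the 4 Klotho values lay below the 4 control values, an arrangement found in 2.83% of all genes against 1.43% by chance. A symbol was available for 34 of the 37, and 29 of these are on a list of 77 adult liver genes drawn up after the result was seen (0.13 expected, Fisher's exact p = 5.92e-69, two-sided and not independent evidence since the list followed the result). The other 5 are absent from that list, which does not hold every liver gene, so they do not show a response outside liver genes. Also chosen after their values were seen, they were Vtn (vitronectin, at least 3.40-fold lower, adjusted p = 0.0115), Pzp (at least 5.58-fold, 0.0354), Mup4 (log2 change -2.78, 0.0346, above background on 1 Klotho array), Wfdc21 (0.0195) and Cyp2a12 (0.0176). Of the 60 listed liver genes tested, 54 had a negative change, with a median of -2.22, or -1.39 with genes that were not well above background in Klotho set at their bound. Genes that missed the threshold on the lower side included Mup3, at least 2.19-fold lower (adjusted p = 0.0541), the urate oxidase gene Uox, at least 2.48-fold (0.0541), Serpinf2, at least 1.87-fold (0.0718), and the liver enzyme genes Ugt2b38, Cyp2d10 and Rdh7 (0.0574 to 0.0675). On the higher side nothing passed. The smallest p-values belonged to Map6d1 (log2 change 0.50, adjusted p = 0.313), Irak2 (0.68, 0.411), Zfp282 (0.57, 0.641), Mau2 (0.41, 0.641), Slc4a9 (0.41, 0.679), Nrp (0.56, 0.679), Tex101 (0.64, 0.726), Nxnl1 (0.84, 0.782), Cym (0.49, 0.788) and Mesp1 (0.41, 0.818). With the replicate number as a block 24 genes were lower, 21 of them among the 37, and without control 3, control 4 or Klotho 1 the count was 20, 18 and 20. It was 9 with another background correction, 4 among genes above background on all 8 arrays, 63 in the deposited value table and 1 without the liver list, and without the background filter 3862 genes were higher and 165 lower.

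Energy metabolism was the theme of the series, and in neurons no glycolysis or respiration gene passed the test singly. The 20 glycolysis enzymes divided into 11 positive and 9 negative changes with a median of 0.01 (limma camera, adjusted p = 0.960). Their members with the smallest p were Pfkl (0.28), Hk2 (-0.46), Ldha (-0.14) and Pfkfb4 (-0.14), with adjusted p of 0.988 to 0.990. Oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, passed camera on the lower side (camera adjusted p = 0.000722). Of their 47 changes 43 were negative, with a median of -0.12 against -0.03 over all tested genes. That call was lost when the correlation between genes was estimated (adjusted p = 0.985 with an estimated correlation), no member passed even when adjusted over the list alone, and in the deposited value table, which divides by each array's SD, the same list had a median of 0.04 and a call in the other direction (adjusted p = 4.97e-10). There the glycolysis enzymes also had a positive call (median 0.08 SD units, adjusted p = 1.77e-05). The members with the smallest p were Uqcrb (-0.29), Ndufa8 (-0.20), Atp5h (-0.18) and Ndufb3 (-0.18). Glucose and lactate transporters had 10 negative changes among 12 and a median of -0.18 (camera adjusted p = 0.173). The mean of this list was lower on all 4 Klotho arrays than on any control array (exact permutation p = 0.0286, two-sided and the smallest possible, adjusted p = 0.737 over 43 lists). Slc16a4, a monocarboxylate carrier, was the 1 member lower when adjusted over the list alone (-1.30 ± 0.28, above background on 2 Klotho arrays), and its adjusted p over all genes was 0.450.

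Besides oxidative phosphorylation, 4 of the 43 gene lists fixed beforehand passed camera on the lower side in neurons, each at an adjusted p of 0.0458. All 4 had adjusted p = 0.985 with an estimated correlation, and fry gave 0 lists. The median over all tested genes was also negative, at -0.03. Lists that were not called ranged from ependymal and choroid plexus markers at -0.21 to microglia markers at 0.09, so a negative median is not particular to the called lists. Genes of glutamate uptake and astrocyte metabolism had 15 of 16 negative changes with a median of -0.14, led by the potassium channel gene Kcnj10 (-0.40), the water channel gene Aqp4 (-0.31) and Aldh1l1 (-0.28). Astrocyte markers had 16 of 19 negative changes (median -0.20), among them S100b (-0.33). TGF-beta target genes had 17 of 18 (median -0.22), including Ltbp1 (-0.51) and Skil (-0.22). Cell cycle genes had 25 of 27 (median -0.22), including the proliferation marker Mki67 (-0.49) and the replication helicase gene Mcm3 (-0.35). None of these members passed the test, also when adjusted over the list alone. Complement C3 was the 1 member of the NF-kappaB list lower when adjusted over the list alone (-1.09 ± 0.23, adjusted p over all genes 0.379). The number of lists was 1 with median scaling, 0 with quantile scaling and 0 without both replicate 1 arrays, and it was 1, 2, 8 and 3 without control 2, control 3, control 4 and Klotho 4.

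No gene of the Klotho receptor complex passed the test in neurons. Kl itself was well above background on at most 2 of the 16 arrays and the related Klb on at most 1. Among the FGF receptors, log2 changes were -0.13 ± 0.24 for Fgfr1, 0.11 ± 0.12 for Fgfr2, -0.33 ± 0.13 for Fgfr3 and -0.35 ± 0.25 for Fgfr4 (adjusted p of 0.988 to 0.995). All neuron arrays shared slide 1, with controls in row 1 and Klotho in row 2 of the slide, so treatment and array row cannot be told apart.

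In astrocytes by scanner file, the NF-kappaB list had the largest median change of the 43 lists, although no single gene passed the test. Of 26 NF-kappaB target genes 25 had a positive change, with a median of 2.96 (camera adjusted p = 8.06e-28, and adjusted p = 0.393 with an estimated correlation). Interleukin-6 (Il6) had a log2 change of 7.87 ± 1.55 and was above background on 3 control arrays, the chemokine gene Cxcl1 6.89 ± 1.48, the nitric oxide synthase gene Nos2 4.65 ± 1.16 and Ccl5 4.47 ± 1.01, each with the 4 Klotho values above the 4 control values and an adjusted p of 0.9999. Interferon response genes were positive in 28 of 28 (median 1.03, camera adjusted p = 7.89e-19, and adjusted p = 0.425 with an estimated correlation), with Rsad2 at 3.80, Cxcl10 at 3.34 and Ifih1 at 1.18. The array-by-array plot of the NF-kappaB list shows 3 of the 4 Klotho arrays above all controls and 1 among them (exact permutation p = 0.0857, two-sided, adjusted p = 0.410 over 43 lists). Extracellular matrix genes and insulin and IGF signalling genes had all 4 Klotho arrays above the controls (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.410).

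**Figure D2:**
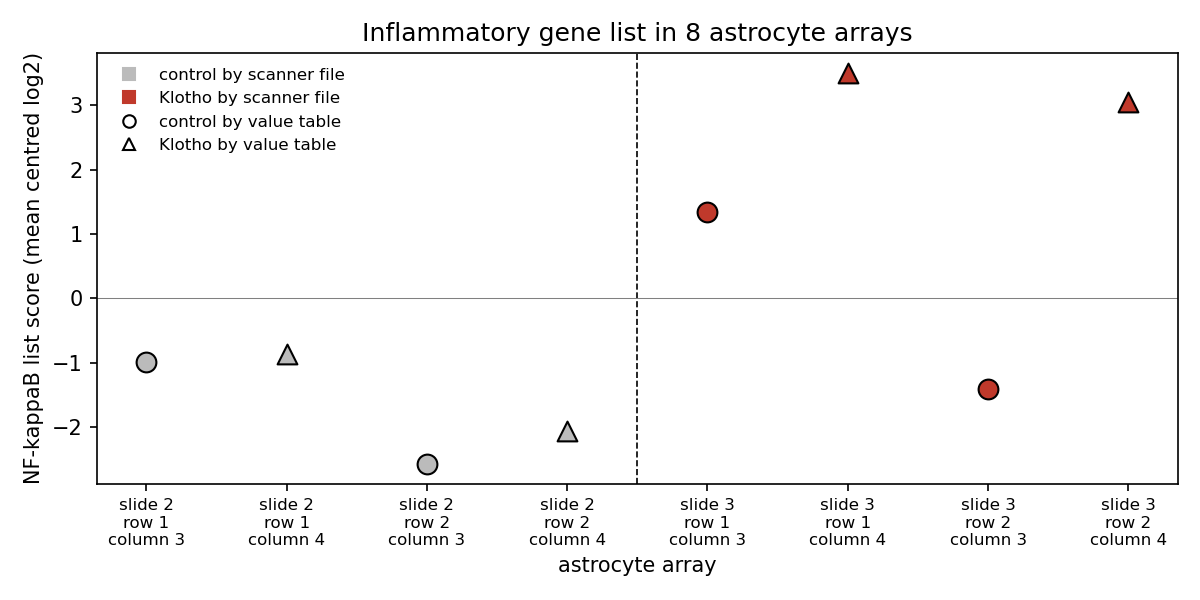
NF-kappaB list score (mean of the centred log2 values of its genes) on the 8 astrocyte arrays, ordered by slide, row and column. Colour gives the treatment by scanner file and shape the treatment by value table. Scores on slide 2 lie between -2.57 and -0.87, and on slide 3 they are 1.34, 3.50, -1.40 and 3.04.

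Of 23568 genes tested in astrocytes by scanner file, limma called 0, and the smallest adjusted p was 0.9999. An unadjusted p below 0.05 was found for 892 genes, against 1178 expected by chance. With array row as a block, added after the data were seen, limma also called 0, and 2619 genes had an unadjusted p below 0.05. The 4 values of each treatment did not overlap in 2.55% of genes against 2.86% by chance. None of the following genes passed. On the higher side the smallest p-values were those of the glycosyltransferase gene A4galt (1.77), the cytokine gene Csf2 (at least 133.5-fold higher), the interferon gene Ifnb1 (7.42), Mest (1.96), Dusp5 (2.21), Il6, Cxcl9 (6.27), Slc26a9 (1.82), Cxcl1 and Slitrk4 (1.69). Ifnb1 and Slc26a9 were above background on 1 control array, and A4galt, Dusp5 and Cxcl9 on 2. On the lower side they were those of the semaphorin gene Sema3d (-1.17), the myelin gene Mag (-1.61), Nlrp4f (-1.27), the oligodendrocyte transcription factor gene Sox10 (-1.45), Acap1 (-1.09), Spire2 (-0.97), Gabre (at least 1.71-fold lower), Atp6v1g2 (-0.96), Cd300ld3 (level -4.75 in control and -5.75 with Klotho) and Fxyd7 (-0.94). Sema3d, Nlrp4f and Cd300ld3 were above background on 1 Klotho array, Acap1 on 2 and Fxyd7 on 3. Without control 3 the count was 1 and without Klotho 3 it was 11, all higher, and a fit of all 16 arrays together called 2.

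Camera placed 17 lists past the threshold in astrocytes by scanner file, 15 higher and 2 lower, and none of these calls held with an estimated correlation or by fry. The estimated-correlation test also called 0 lists between the controls, so the loss there does not decide, while fry called 36 between the controls. In the deposited value table, which follows its own assignment, 20 lists passed, 6 higher and 14 lower, and of the 10 called in both, 4 had the opposite direction (oxidative phosphorylation, cholesterol synthesis, lysosome and autophagy, and ribosomal proteins). Extracellular matrix genes were positive in 35 of 37 (median 0.61, camera adjusted p = 1.45e-13, and adjusted p = 0.213 with an estimated correlation), with Adamts1 at 1.57, Postn at 1.28 and the collagen gene Col1a2 at 1.20. Cholesterol synthesis genes were positive in 19 of 24 (median 0.45, adjusted p = 0.425 with an estimated correlation), with Fdps at 0.71. Activity-regulated genes had a median of 0.65 (adjusted p = 0.474 with an estimated correlation) with Egr2 at 3.14 but Nr4a2 at -0.71, and FGF-ERK target genes had 0.42 (adjusted p = 0.393 with an estimated correlation). Reactive astrocyte markers had a median of 0.47, with Ptx3 at 4.50 (adjusted p = 0.466 with an estimated correlation). All 39 ribosomal protein genes were positive (median 0.33, adjusted p = 0.756 with an estimated correlation). Oxidative phosphorylation was higher by camera (median 0.12, adjusted p = 0.0306, and adjusted p = 0.861 with an estimated correlation). The remaining lists on the higher side were ATF4 and unfolded protein response (median 0.28), TGF-beta targets (0.33), GABA signalling (0.17) and lysosome and autophagy (0.17), with estimated-correlation adjusted p of 0.393 to 0.756. Adjusted over the list alone, 18 NF-kappaB genes, 6 interneuron genes and 1 FGF-ERK target were higher and 2 oligodendrocyte genes lower, against 0 over all genes.

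Lists of markers of other cell types passed camera in this grouping. No single marker passed limma, and no list held with an estimated correlation. Interneuron markers had a median of 0.88, with Slc32a1 at 2.48, Sp8 at 1.68, Dlx1 at 0.88 and Gad1 at 0.70 (adjusted p = 0.298 with an estimated correlation), of which Slc32a1 was above background on 2 control arrays and Sp8 on 3. Oligodendrocyte lineage markers were negative in 13 of 18 (median -0.22, camera adjusted p = 0.00371, and adjusted p = 0.425 with an estimated correlation), with Gpr17 at -2.64 (above background on 3 Klotho arrays), Mag at -1.61, Sox10 at -1.45 and Cldn11 at -0.99. Microglia markers were negative in 17 of 21 (median -0.26, adjusted p = 0.0104, and adjusted p = 0.692 with an estimated correlation), with C1qa at -0.47 and Cx3cr1 at -0.42. Meningeal fibroblast markers had a median of 0.24 (adjusted p = 0.00907, and adjusted p = 0.425 with an estimated correlation). Treatment and slide cannot be told apart in this grouping, and slide 3 held every Klotho array.

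By value table the astrocyte comparison had lipid synthesis lists on the lower side by camera, while activity-regulated genes were on the higher side as by scanner file. No gene passed limma, and no list call held with an estimated correlation or by fry. Activity-regulated genes were positive in 24 of 26 (median 0.91, camera adjusted p = 6.87e-15, and adjusted p = 0.337 with an estimated correlation), with Fosb at 1.81, Arc at 1.52, Ier2 at 0.94 and Dusp1 at 0.71. NF-kappaB genes were again positive, in 25 of 25 (median 1.83, adjusted p = 2.24e-12, and adjusted p = 0.547 with an estimated correlation), with Lif at 2.32, Birc3 at 1.83 and Relb at 1.06. Fatty acid synthesis genes were negative in 14 of 14 (median -0.45, adjusted p = 8.82e-06, and adjusted p = 0.337 with an estimated correlation), with the desaturase genes Scd2 at -0.72, Fads1 at -0.70 and Fads2 at -0.63. Cholesterol synthesis genes, positive by scanner file, were negative in 22 of 24 here (median -0.38, adjusted p = 3.56e-05, and adjusted p = 0.547 with an estimated correlation), with Sqle at -0.68 and Nsdhl at -0.48.

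In total 12 lists passed camera by value table, 6 higher and 6 lower, and 7 of the 12 were also called by scanner file, 6 in the same direction and cholesterol synthesis in the opposite one. Astrocyte markers (median -0.35) and genes of glutamate uptake and astrocyte metabolism (median -0.23) were lower, with Kcnj10 at -0.81, the connexin gene Gja1 at -0.66 and Sox9 at -0.57 (adjusted p = 0.337 with an estimated correlation for both). Ependymal and choroid plexus markers had a median of -0.45 (adjusted p = 0.472 with an estimated correlation). Interferon response genes (0.57), reactive astrocyte markers (0.52), FGF-ERK targets (0.33) and extracellular matrix genes (0.20) were higher, with estimated-correlation adjusted p of 0.430 to 0.817. No gene passed limma among 23423 (smallest adjusted p = 1, 546 with an unadjusted p below 0.05), also with slide as a block (636) or with slide and row together (3163). The number of unadjusted p-values below 0.05 expected by chance was 1171. The smallest p-values included those of Atp8b3 (1.01, above background on 1 control array), Rapgef5 (0.94) and the transcription factor gene Runx1 (1.36) on the higher side, and Rax (-1.21), the endothelin receptor gene Ednra (-1.01), the chemokine receptor gene Cxcr4 (-1.32) and Dio3 (-0.95) on the lower side. With slide and row as blocks the number of lists was 11. Within slide 2 the mean NF-kappaB score was -1.78 in the 2 control arrays and -1.46 in the 2 Klotho arrays, and within slide 3 it was -0.03 and 3.27.

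No glycolysis gene passed the test in astrocytes under either assignment, and the group showed no shift by camera. By scanner file the 20 enzymes had 8 positive and 12 negative changes with a median of -0.06 (camera adjusted p = 0.979), and Pfkfb3 (0.44), Pfkl (-0.27), Eno2 (0.60) and Pfkfb4 (-0.43) had the smallest p. The mean of the list differed by 0.01 (exact permutation p = 0.943, two-sided). By value table the median was -0.10 (camera adjusted p = 0.836), with Hk2 at 0.99, Eno2 at 0.69, Pfkm at -0.30 and Gpi1 at -0.20, and the exact permutation p of the list mean was 0.857. Glucose and lactate transporters had a median of 0.00 by scanner file (camera adjusted p = 0.295), with Slc2a6 at 1.50, Slc16a4 at 0.61, Slc2a4 at 0.40 and Slc16a3 at 0.14. By value table they were negative in 9 of 12 (median -0.26, camera adjusted p = 0.0228, and adjusted p = 0.337 with an estimated correlation), with none past limma. Among them were Slc16a4 at -0.92, Slc2a10 at -0.69 and the main glucose carrier gene Slc2a1 at -0.69. The FGF receptor genes differed by 0.20 (Fgfr1), -0.09 (Fgfr2), -0.36 (Fgfr3) and 0.32 (Fgfr4) by scanner file, and by -0.17, -0.14, -0.39 and 0.19 by value table, none past the test. In a simulation with the spread of the astrocyte arrays, 3% of genes changed by 1 on the log2 scale and 43% of those changed by 2 were recovered. Its noise was independent between genes and arrays, unlike the row pattern of the real arrays, so these shares need not hold for them.

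**Figure D3:**
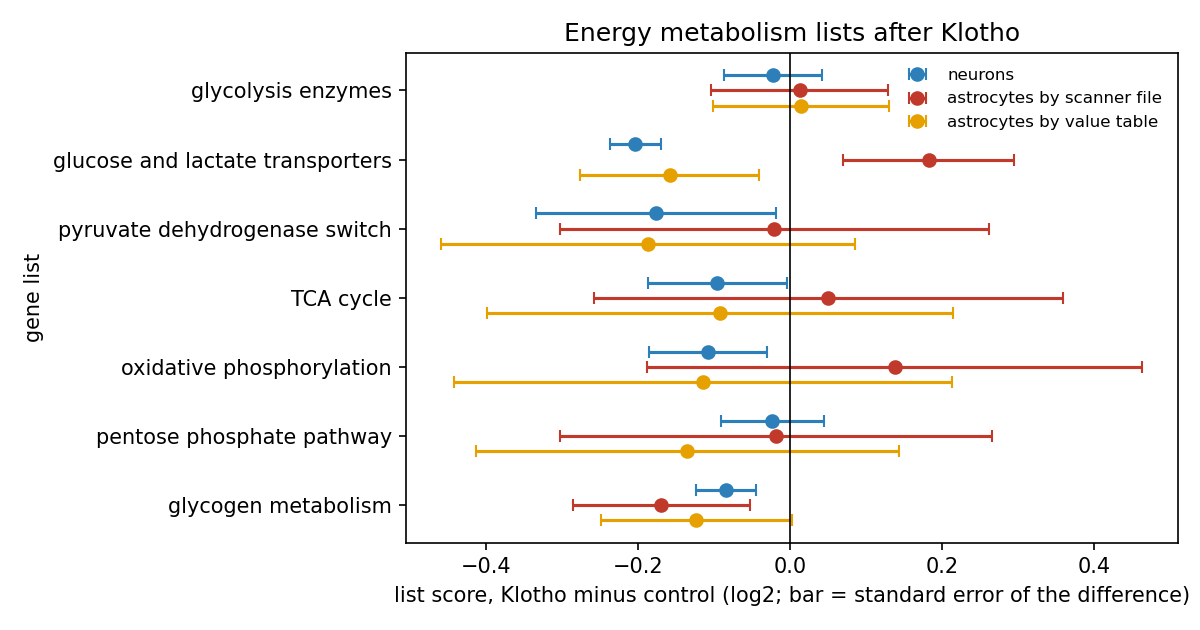
Mean expression of 7 energy metabolism lists, Klotho minus control on the log2 scale, for neurons, astrocytes by scanner file and astrocytes by value table. Bars give the standard error of the difference (n = 4 arrays per group). The glycolysis enzymes lie at -0.02 in neurons and 0.01 under both astrocyte assignments.

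The 4 astrocyte arrays whose treatment is the same in both assignments gave a median of 5.26 for the NF-kappaB list (camera adjusted p = 2.26e-63, adjusted p = 0.991 with an estimated correlation, fry adjusted p = 0.484). The slide 3 arrays left out are those with the lowest NF-kappaB scores of that slide, 1.34 and -1.40. With array row as a term, an alternative added after the conflict was seen, 228 of 24210 genes were higher and 8 lower with Klotho. Csf2 was at least 632.6-fold higher (adjusted p = 6.47e-05) and Ifnb1 at least 316.6-fold (7.88e-05). Cxcl1 rose by 9.40 ± 0.63 (adjusted p = 0.000840), the cyclooxygenase gene Ptgs2 by 7.53, Nos2 by 6.81 and Tnf by 6.17, while the oligodendrocyte gene Bcas1 fell by 2.76 (0.0181) and Dscam by 2.34 (0.0390). These genes were chosen after their values were seen, and the fit rests on 2 arrays per treatment, which lay on different slides and in different slide columns, so neither can be told apart from treatment.

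The interaction term called 23 of 26136 genes by limma, 21 with a higher and 2 with a lower fitted effect in astrocytes. An unadjusted p below 0.05 was found for 1375. Of the 21 genes 19 are on the adult liver list. The count therefore mostly repeats the neuron difference, which cannot be told apart from array row. The smallest adjusted p belonged to liver genes. They were Ahsg and Alb (adjusted p = 1.82e-05 each), Mup1 (4.99e-05), Mup17 (6.43e-05) and Serpina1e (7.43e-05). Alb, Ahsg, Mup1 and Mup17 were not well above background on any astrocyte or neuron Klotho array and Serpina1e on 1 astrocyte array, so the fitted differences rest partly on background signal and measure no size. In neurons Mup1 was at least 12.2-fold and Mup17 at least 8.38-fold lower with Klotho. In the lower direction the olfactory receptor gene Olfr103 had a fitted difference of -1.83 that also rests partly on background signal (adjusted p = 0.0282, above background on 3 astrocyte control and 0 astrocyte Klotho arrays). It became -0.26 (adjusted p = 0.9999) by value table and 0.06 (adjusted p = 0.965) in the deposited values. With the assignment of the value table, 19 genes differed, all higher. Without the listed liver genes 1 gene remained past the threshold, among genes above background on every array 0 (limma, 867 with an unadjusted p below 0.05), and without astrocyte Klotho 3 or neuron control 2 the count was 148 and 36.

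Lists with a different effect in astrocytes numbered 18 by camera (17 higher, 1 lower), 0 with an estimated correlation and 1 by fry. By value table they numbered 8 (7 higher, 1 lower), 0 with an estimated correlation and 0 by fry. The NF-kappaB list had a median difference of 3.26 (camera adjusted p = 4.07e-24, and adjusted p = 0.322 with an estimated correlation), and 17 of its 26 genes were higher when adjusted over the list alone. Extracellular matrix genes had a median of 0.69 (adjusted p = 3.84e-11, and adjusted p = 0.0669 with an estimated correlation), the list that fry called (adjusted p = 0.0399, but 0.998 by value table, where the estimated-correlation adjusted p was 0.978). Glycolysis enzymes had a median difference of -0.04 (adjusted p = 0.949).

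The vehicle-treated cultures differed in the markers of their cell types, and this comparison serves as a check of the labels. All 22 neuron markers were negative in astrocytes relative to neurons and 21 were lower by limma, with a median of -6.49, or -6.07 with genes at their bound. The neurofilament gene Nefl was at least 708-fold lower and the transcription factor gene Neurod6 at least 439-fold. Dcx (-10.08) and Neurod2 (-10.01) were above background on 2 and 1 astrocyte arrays. Of 20 astrocyte markers 14 were higher and 1 lower (median 1.58), with the filament gene Gfap at 5.75 ± 0.49, Gjb6 at 3.21 ± 0.36 (above background on 1 neuron array), Aqp4 at 2.99 ± 0.29 and S100b at 2.94 ± 0.40 (adjusted p = 0.000235 or smaller).

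The same comparison showed other cell types in both cultures. Of 21 microglia markers 19 were higher in the astrocyte cultures, with Ctss at 7.80, the fractalkine receptor gene Cx3cr1 at 7.32, Tmem119 at 6.97 (above background on 2 neuron arrays) and the complement gene C1qa at 6.83. Reactive astrocyte markers were higher in 27 of 29, with C3 at 8.51, Cd109 at 7.73 and Cp at 7.36. Meningeal fibroblast markers were higher in 10 and lower in 4 of 17, with Ogn at 6.79, Col1a2 at 5.78 and Col3a1 at 4.03, and endothelial and pericyte markers were higher in 7 and lower in 3 of 14, with Vwf at 4.60 and Pdgfrb at 4.53. Ependymal and choroid plexus markers were higher in 12 and lower in 1 of 17, with the cilia regulator gene Foxj1 at 5.37. The choroid plexus gene Ttr, at -5.66 (above background on 3 astrocyte arrays), is also on the adult liver list. Of 60 tested genes on that list 44 were lower and 7 higher in the astrocyte cultures (median -2.50, or -1.74 with bounds). Interneuron markers were lower in 14 of 17, with somatostatin (Sst) at least 4229-fold lower, and with Cck at -13.29, Slc32a1 at -11.90 and Gad2 at -8.88, above background on 1, 2 and 2 astrocyte arrays. Oligodendrocyte lineage markers were lower in 7 and higher in 1 of 18, with Pdgfra at -3.75, Olig2 at -2.28 and Sox10 at -2.14. Neural progenitor markers were higher in 6 and lower in 6 of 17, with Prom1 at 3.83 and Hes5 at -8.59, while Eomes and Neurog2 were at least 20.2-fold and 10.2-fold lower.

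Metabolic and receptor genes also differed between the control cultures by scanner file. Glycolysis enzymes were higher in 3 and lower in 4 of 20 without a shift of the group (camera adjusted p = 0.971), while glucose and lactate transporters were higher in 5 and lower in 3 of 12. Slc2a1, the glucose carrier of glia and endothelium, was higher in astrocytes by 3.42 ± 0.24, and the neuronal carrier gene Slc2a3 was lower, at -2.49 ± 0.27. The hexokinase gene Hk2 was higher by 3.06 ± 0.26, Ldhb by 1.46 ± 0.31, and Ldha was lower, at -1.12 ± 0.31 (adjusted p = 0.0139). These 5 genes were chosen after their values were seen. Fgfr1 (1.54), Fgfr2 (1.54) and Fgfr3 (1.28) were higher in astrocytes (adjusted p = 0.000870, 4.96e-05 and 0.000469), and Fgfr4 had -0.37 (adjusted p = 0.556). In all, 13848 of 26018 genes differed by limma, 5807 higher and 8041 lower, and 14207 (54.6%) had groups without overlap against 2.86% by chance. Camera called 24 lists, 16 higher and 8 lower, of which 0 held with an estimated correlation (smallest adjusted p = 0.0510), while fry called 36. The median change of all genes was -0.22 and moved by 0.11 with quantile scaling, and cell type and slide cannot be told apart.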

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

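The tests of liver and blood RNA, of the inflammatory genes on slide 3, of other splits for single astrocyte genes, and of splits that part the numbered pairs for the interaction were chosen only after the result was seen.

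Genes of the adult liver were high in the neuron control arrays and low in the Klotho arrays, with Alb at a mean of 0.18 ± 0.85 (SD) in controls and all 37 called genes lowest in control 2 (median -1.37 against the other controls). Over all 35 splits, which ignore the pairing, only the real one gave calls, a share under 0.05 (37 genes, 0 in the highest other). The 8 splits that part all 4 numbered pairs are too few for a share under 0.05 (37 genes, 0 in the highest other). Chance is therefore not excluded where the pairing is kept. The Klotho arrays had fewer spots well above background (mean 59.4% against 66.6% in controls). Lower sensitivity as the source of the low liver genes is argued against by 714 uncalled genes of the same control level. They changed by a median of -0.012 (quartiles -0.14 and 0.13), against -3.24 for the called genes. RNA of red cells, from embryonic liver or blood, is argued against by a median of 0.024 over 5 genes. These were Hba-a1, Hba-a2 (0.02), Hbb-bh1, Epor and Slc4a1, which do not cover the other cells of embryonic liver. For those cells there was only Afp, with 1 probe, above background on 0 neuron arrays, which is too little to decide. RNA of adult liver in the controls is a candidate source. The 31 listed genes that were not called had a median of -1.03 (-0.77 with bounds), and 80.6% were lower, against 50.6% of level-matched genes. They are no independent set, since the list followed the result and 16 of them were lower with an unadjusted limma p below 0.05. An effect of Klotho or of array row on liver genes would give the same fall, so these values do not tell the sources apart. Of the listed genes 21 were above background on all 4 Klotho arrays, 19 on all 8 astrocyte arrays and 1 is on another list. An effect of Klotho on these genes was not tested apart from the array row and stays open, and the labels record no sort that would remove other tissue.

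Inflammatory genes were high on 3 of the 4 astrocyte arrays of slide 3, with NF-kappaB scores of 1.34, 3.50, -1.40 and 3.04 against -2.57 to -0.87 on slide 2. A larger share of microglia on slide 3 is argued against by a median of -0.262 for 21 microglia markers. Of these 4 were higher, and the largest change was 0.21. These changes compare means of 4 arrays, including the slide 3 array with a score of -1.40. They do not address the state of the microglia. Klotho or slide by scanner file cannot be told apart, as both name the same arrays, and 3 slide 3 arrays lay above all of slide 2. Klotho by value table, confounded with slide column, stays open too, since 2 of its Klotho arrays had a score below the highest control, and the bounds set for both assignments rested on single arrays, too few to decide. The splits say nothing on single genes, with 0 calls in the real split under either assignment (the highest other, 10791, follows the array rows and keeps the numbered pairs together), and for gene lists chance cannot be excluded by scanner file (17 lists against 20 in the highest other split; 6 of the 35 splits gave as many) or by value table (12 against 20).

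The interaction term called 23 genes between the cell types, 19 of them on the adult liver list. It gave fitted differences of 6.40 for Ahsg, 6.77 for Alb, 5.45 for Mup1, 5.40 for Mup17, 6.16 for Serpina1e and -1.83 for Olfr103. These are no measured sizes, since Alb, Ahsg, Mup1 and Mup17 were above background on 0 astrocyte arrays, Serpina1e on 1 and Olfr103 on 0 of the astrocyte Klotho arrays. Of 100 drawn splits that ignore the numbered pairs, 4 gave at least 23 genes, the real one included. This share is under 0.05 but too near it for these draws alone to exclude chance. The highest other split called 8220, which points to a structure of the samples. Among 100 drawn splits that part all 4 numbered pairs in both cell types, as the real one does, the highest other gave 26 and 2 gave as many as the real one, itself included.

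Some values (log2 levels unless stated) lay far from the other 3 of their group, and chance gives about 1 in 20 groups, so 16 of the 310 groups looked at against 24 found. On neuron control 1 these were Fgfr1 (4.10), Gad2 (3.53), Ifit3 (-4.47), Pdgfrb (-2.99), Prom1 (-0.15), Slc32a1 (6.70) and the number of spots well above background (38541). On neuron control 2 they were Cyp2a12 (-6.24), Olig2 (2.86) and Serpinf2 (-5.00). Among the neuron Klotho arrays they were Aqp4 (1.25), Fgfr1 (3.99) and Fgfr2 (-1.18) on array 1, Serpina1e (-4.33) on array 3 and Serpina1a (-4.71) on array 4. Astrocyte control 4 had Aqp4 (3.80), Egr2 (-1.02), Fads1 (2.42), Fads2 (-0.88) and Hmgcs1 (3.52), and control 3 had Nos2 (-2.30). The others were Nr4a2 on astrocyte control 1 (-0.97), Slc2a4 on control 2 (2.32) and Cxcl9 on astrocyte Klotho 3 (-4.03).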

How the results depend on the processing

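Added after the data were seen were the value table assignments, the row and slide blocks, the fits without liver genes or without both replicate 1 arrays, and individual array weights. The fixed slide block was not run by scanner file, where slide is confounded or shared by all arrays. The cause of a change was not tested unless given. The neuron count of 37 genes was 9 with normexp, 4027 without a filter (3862 higher), 4 for genes above background on all arrays (fewer genes tested), 63 in the deposited value table, 24 with the replicate block, 1 without adult liver genes and 16 without both replicate 1 arrays (fewer arrays); it was within 1.5 times in 5 of 12 alternatives and 18 to 49 without single arrays. The 5 neuron lists became 0 with an estimated correlation, by fry, with quantile scaling and without both replicate 1 arrays, 1 with median scaling, 14 without a filter, 2 with probe means and 16 in the deposited values (10 higher and 6 lower, against 0 and 5; 1 to 8 without single arrays). The 0 astrocyte genes (limma, 892 unadjusted) became 2 with all 16 arrays in 1 fit and 236 on the 4 arrays with the same group in both assignments (0 to 11 without single arrays). The 17 astrocyte lists became 0 with an estimated correlation and by fry and 11 by value table with slide and row blocks, and in the deposited values they were 20, of which 14 lower against 2 (12 to 19 without single arrays). The 23 interaction genes became 9 with normexp, 0 above background on all arrays (limma, 867 unadjusted), 42 in the deposited values, 14 with per-group array weights, 1 without adult liver genes and 10670 with individual weights (17 to 148 without single arrays), and Olfr103 turned to 0.06 in the deposited values. The controls count stayed within 1.5 times in 11 of 11 alternatives (10875 to 15176, and 11930 to 13822 without single arrays). The replicate block changed no other call by over 1.5 times: it gave 0 astrocyte genes (limma, 2234 unadjusted), 28 interaction genes, 13038 between controls, and 5 and 17 lists. Signal over background limits dim genes, of which 27 of the 37 neuron genes were not above background on any Klotho array.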

Other observations

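The tests of array position and of the sex of the culture pools were chosen only after the result was seen, as were the genes named here.

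Control astrocytes by scanner file and control neurons also differed in pathways outside the marker lists. All 28 interferon response genes were higher in astrocytes, with a median of 6.26 (6.22 with bounds), among them Ifit3 (8.53) and Isg15 (5.52). Of 20 TGF-beta targets 16 were higher and 2 lower (median 2.82), with Tgfbi at 5.66, and 14 of 19 fatty acid oxidation genes were higher (median 1.17), with Cpt1a at 2.00. Presynaptic vesicle genes were lower in 17 of 20 (median -4.46), with Syn1 at -5.81, and ionotropic glutamate receptor genes lower in 19 and higher in 1 of 24 (median -3.57, or -3.45 with bounds), with Gria2 at -3.80. Oxidative phosphorylation genes were lower in 29 of 47 (median -0.87), ribosomal protein genes in 29 of 39 (-1.14) and cholesterol synthesis genes in 15 of 24 (-1.45), with Hmgcs1 at -2.71. By estimated-correlation camera none of these lists passed (adjusted p = 0.0510 for TGF-beta targets, 0.244 to 0.629 for the others). Of 35 splits of the control arrays only the real one gave calls, 13848 genes against 0 in the highest other. This share is under 0.05 and the smallest that these splits can give. Every other split mixes the 2 cell types within its groups, which widens their spread, so few calls were likely there beforehand.

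The largest difference among the astrocyte arrays lay between the rows of the slides, not between treatments. Of 23676 genes 10791 were called between the 4 arrays of row 2 and the 4 of row 1, 4844 higher and 5947 lower in row 2. This fit treats the arrays as independent, although same-numbered arrays lie in the same row. All 39 ribosomal protein genes were lower in row 2 (median -1.06), with Rplp1 at -1.12, and so were 37 of 47 oxidative phosphorylation genes (-0.76), with Ndufa4 at -0.76, and 13 of 18 TCA cycle genes (-0.72), with Sdhd at -1.45. Interferon response genes were lower in 10 of 28 (-1.24) and cell cycle genes in 14 of 28 (-0.48). Calcium handling genes were higher in 9 and lower in 2 of 18 (0.82), with Cacna1c at 1.28, and ionotropic glutamate receptor genes higher in 7 of 20 (0.70), with Gria2 at 2.10. By estimated-correlation camera these lists had adjusted p of 0.876 to 0.879. The first principal component of the astrocyte arrays (59.5%) separates the rows, and that of the neuron arrays (56.6%) separates replicate 1 of both groups from the rest.

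Array position and sex of the pools were weighed for this row pattern. Position on the slide is argued against by a correlation of 0.041 (Spearman 0.052) over 22156 genes between the row differences of the astrocyte and neuron arrays, although in neurons the rows are also the treatments. Pools of different sex are argued against by a mean difference of -0.015 ± 0.252 (SE) over 3 Y-linked genes, although Xist was higher in row 2 by 1.52 (lowest 0.83 in row 2, highest 0.72 in row 1). Separate culture or labelling batches may underlie the rows, but the labels name none, and no other biological explanation was tested.

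For the 5 gene lists of the neuron comparison chance cannot be excluded, since the highest other split gave 21 and 25 of 35 splits gave as many. Among the 8 splits that part all 4 numbered pairs the highest other gave 13.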
